A study of Mus musculus with 4 samples.

How the data were processed

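RNA sequencing was carried out on B cells of bone marrow from C57BL/6 mice aged 8 to 12 weeks, per the labels. The cells were sorted as Fr.C+C′, a gate that in the Hardy scheme of bone marrow B cell development holds late pro-B and early pre-B cells. Per the labels, 2 libraries came from wild type mice (WT 1, WT 2) and 2 from mice labelled as ADAR1 knockouts (KO 1, KO 2). ADAR1, encoded by Adar, converts adenosine to inosine in double-stranded RNA. Per the labels' protocols, RNA was extracted from sorted cells with Trizol, and 1 µg of total RNA with a RIN value (a score of RNA integrity) above 6.5 entered an Illumina library preparation. Whether strand was kept and whether poly(A) selection was used is not given in the sources used here. Nothing in the labels says whether the 2 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

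The authors deposited, for each library, FPKM values (fragments per gene scaled to exon length and to the fragments of the library) for 55573 mouse Ensembl gene identifiers, rounded to 2 decimals, per the file headers. The genome build named in the submitters' processing notes is mm9. The identifiers deposited include ones newer than annotations of that build, and their implied lengths matched the union of exons in GENCODE M21, an annotation of the GRCm38 build. The aligner and the counting program are not given in the sources used here. Symbols were found for 55394 identifiers, and coordinates in the text are 1-based GRCm38 positions from GENCODE M21, since the files give none.

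Depth was recovered from the low values. FPKM multiplied by union exon length fell on whole multiples of the value of 1 fragment in 99.5%, 99.5%, 99.6% and 99.5% of the values checked in WT 1, WT 2, KO 1 and KO 2, within a tolerance of 0.15 fragments, where chance gives 30%. These steps gave 15792087, 16402676, 15832544 and 15110945 fragments assigned to genes. For a transcript of 1000 nt, 1 fragment was then worth 0.0633, 0.0609, 0.0631 and 0.0661 FPKM, so values below about 0.2 FPKM rest on 3 fragments or fewer at that length. Fragments given for single genes below are estimates from these steps and cover counting error only. Library pairs differed by more than sampling noise (chi-square per degree of freedom of 8.45 for WT 1 with WT 2 and 61.6 for KO 1 with KO 2), so no library was a copy of another.

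Because the files hold FPKM and not counts, the test was limma (version 3.58.1, R 4.3.3) on log2(FPKM + 1), with a mean-variance trend and no covariate, over genes with a mean of at least 1 FPKM in either group. Log2 changes are KO minus WT on this scale, which understates changes of low genes, and errors given with them are standard errors from the same model. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. With 2 libraries against 2, an exact permutation test cannot give a p below 0.333, so no single gene was tested that way. The test was checked on simulated data with the KO vs WT layout. On 12876 simulated genes it called 35.1% of 97 genes changed 2-fold and 90.9% of 99 changed 4-fold, with 6 false calls. In a separate run on 12858 genes it called 100% of 200 genes changed 16-fold, all drawn from genes of higher expression, with 26 false calls. That is a larger share of the calls than the threshold of 0.05 allows. The simulated noise was independent between genes and alike in both groups. In the data KO 1 and KO 2 differed more (SD across genes of their log2 difference 0.487) than WT 1 and WT 2 did (0.322), which the check does not cover.

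There were 19 pathway lists and 12 lists of markers of other cell types, written before the data were examined, as were the groups, tests, alternatives and the rule for naming genes. Each list was tested with camera of limma, which compares a list with the other genes. The test was two-sided with a preset correlation between genes of 0.01, adjusted over the lists of its kind. It was repeated with an estimated correlation and with fry. Fry is a rotation test of whether the genes of a list move one way on balance without comparing them with other genes. The preset treats the genes of a list as nearly independent, so its p does not measure the spread between libraries. Estimated correlations ranged from -0.035 to 0.945. With them camera has only 2 residual degrees of freedom and gave no unadjusted p below 0.113. Failing it therefore does not show a list to be unchanged. The naming rule took Adar, the 10 largest rises and falls past the threshold with both KO libraries beyond both WT libraries and at least 5 FPKM, leaving out immunoglobulin and T cell receptor segments and unnamed or small RNA genes, then up to 4 members of each list with the smallest p (8 for interferon-stimulated genes), and a fixed set of B-lineage, double-stranded RNA and sex-linked genes, of which 1 is not reported here. Genes outside the rule are said in the text to have been chosen after their values were seen.

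Alternatives planned were the replicate number as a block, leaving out each library in turn, no filter beyond a value above 0, a stricter filter of 5 FPKM, quantile normalization, median centring, a pseudocount of 0.1, no trend, a minimum absolute log2 change of 1, and the other list tests. Added after seeing the data were voom on estimated fragments, scaling to an equal median of the B-lineage list, rescaling to fragments outside the neutrophil list, and a block with the replicate numbers crossed. No label states a pairing, and the block and the crossed block cannot both be one. A gene that passes only with such a block or with a library left out is therefore not counted as a call. Count-based tests planned for count files were not run. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Immunoglobulin V segments share sequence with near-identical copies, so the value of any single segment is uncertain. The same holds for genes with many processed copies, such as Gapdh, listed at 4.2, 4.91, 5.87 and 6.72 FPKM in WT 1, WT 2, KO 1 and KO 2 (chosen after its values were seen).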

Results

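The transcriptomes of sorted Fr.C+C′ B cells were measured in 2 wild type libraries and 2 libraries labelled as ADAR1 knockout, each with between 15110945 and 16402676 fragments assigned to genes. Between 21915 and 22731 genes had a value above 0 in a library, and between 12575 and 12892 reached 1 FPKM. Spearman's rho across genes, which are not independent replicates, was 0.980 between WT 1 and WT 2 and 0.953 between KO 1 and KO 2. KO 2 stood further from the wild type libraries (0.917 and 0.909) than KO 1 did (0.954 and 0.956). Its 10 most abundant genes held 24.0% of all FPKM, against 12.5%, 12.2% and 14.3% in WT 1, WT 2 and KO 1.

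The targeted gene was examined first. Adar (ENSMUSG00000027951, GRCm38 chromosome 3, 89715022 to 89753446) stood at 15.04 and 14.62 FPKM in the wild type libraries and at 15.19 and 16.79 FPKM in the libraries labelled KO, means of 14.8 ± 0.297 and 15.99 ± 1.13 (SD, n = 2). The log2 change was 0.10 ± 0.14 (95% interval -0.25 to 0.45), with an adjusted p of 0.721 in limma. Each library held about 1929 to 2061 Adar fragments. A value over the whole gene cannot show the loss of some exons, so it does not check the knockout label, and it gives no sign of a lower Adar transcript level. Directions below are therefore those of the libraries labelled KO against the wild type libraries. Adarb1, the paralogue encoding ADAR2, was below the filter in every library, at 0.33, 0.26, 0.31 and 0.15 FPKM in WT 1, WT 2, KO 1 and KO 2.

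The comparison asks which transcripts differ in early B cells of mice labelled as lacking ADAR1. With all libraries and no block, the transcripts called lower in the libraries labelled KO were almost all immunoglobulin transcripts. This share depended on the setting. With the crossed block 135 of 213 called genes were immunoglobulin genes and 78 were not, and without KO 1 most called genes were not. Jchain, which encodes the chain joining secreted IgA and IgM and is typical of antibody-secreting cells, fell from 105.85 and 91.45 FPKM to 0.25 and 0.45 FPKM. Its means were 98.7 ± 10.2 and 0.350 ± 0.141 FPKM (SD, n = 2), a 282-fold lower level that rests on about 10 and 17 fragments in the KO-labelled libraries. Fcer2a, the low-affinity IgE receptor CD23 of mature B cells, fell from 3.93 ± 0.148 to 0.195 ± 0.0354 FPKM (SD, n = 2), 20.1-fold. The log2 changes were -6.21 ± 0.16 for Jchain (adjusted p = 0.00135, limma) and -2.04 ± 0.19 for Fcer2a (adjusted p = 0.0476, limma). Jchain (ENSMUSG00000067149) lies on chromosome 5, 88519809 to 88527891, and Fcer2a (ENSMUSG00000005540) on chromosome 8, 3681737 to 3694175. Without KO 2 neither passed (adjusted p = 0.0634 for Jchain and 0.213 for Fcer2a), nor did either with no filter on low values (0.0612 and 0.306). The log2 changes without KO 2 were -6.31 and -2.01, near those with all libraries, and the filter does not alter them. Fcer2a also did not pass without WT 1 (0.160) or WT 2 (0.125), with a pseudocount of 0.1 (0.105), quantile normalization (0.0760), median centring (0.0631), rescaling without the neutrophil list (0.0528) or the replicate block (0.0505).

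Of 13281 genes tested, 27 fell and 0 rose at an adjusted p under 0.05 in limma, and 25 of the 27 were immunoglobulin genes. At an unadjusted p under 0.05 there were 856 higher and 800 lower genes, 1656 in all, where chance alone gives about 664. Both KO-labelled libraries lay above both wild type libraries for 2616 genes and below both for 4204, together 51.4% of genes, where chance gives 33.3%. These chance values are expectations per gene. Genes that move together within a library can exceed them without a group effect, so the excess is no test of the knockout label. The log2 change was negative for 61.7% of all genes tested, with a median of -0.09. Signs and medians of the lists below are to be read against these values. The direction camera gives is relative to the other genes, so it can differ from the sign of a list's median or mean. The number of calls depended on single libraries. It was 0 without KO 2 and 948 (563 higher, 385 lower) without KO 1, and 14 without WT 1 against 29 without WT 2. It was also 0 with no filter on low values, and 9, 0 of them higher, with voom on estimated fragments.

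Of the 25 immunoglobulin genes that fell, 18 were kappa V segments and 4 were constant regions, all of these class-switched. The following genes were chosen after their values were seen. Igha, the constant region of IgA, fell from 304.55 and 216.96 to 0.33 and 0.20 FPKM (log2 change -7.67 ± 0.20, adjusted p = 0.00135). Ighg1 fell from 21.29 and 18.59 to 0.02 and 0.08 FPKM, Ighg2c from 64.43 and 43.64 to 0 and 0.15 FPKM, and Ighg2b from 137.13 and 114.84 to 10.23 and 5.56 FPKM (adjusted p = 0.00293, 0.00364 and 0.0246). The lambda constant region Iglc1, at 91.86 and 41.59 against 4.31 and 2.91 FPKM (log2 change -3.79), and the class-switched Ighg3, at 1.13 and 4.05 FPKM in wild type and listed at 0 in both KO-labelled libraries, did not pass (adjusted p = 0.0701 and 0.345), although Iglc1 did with the replicate block (0.00307), the crossed block (0.00139), the stricter filter (0.0343), B-lineage scaling (0.0180) and without WT 2 (0.0274). Ighm, the constant region of the IgM heavy chain made by early B cells, was at 1385.13 and 1721.93 FPKM against 1151.36 and 502.56 FPKM and did not pass (adjusted p = 0.435). Igkc, the kappa constant region, was at 1727.77 and 1697.43 against 312.56 and 111.12 FPKM (adjusted p = 0.187). Without KO 1 both passed (0.0490 and 0.0426), and Igkc also with the crossed block (0.0105) and B-lineage scaling (0.0204). Of 86 kappa V segments tested, 18 fell, 77 were below both wild type libraries in both KO-labelled libraries, and their summed values were 1536 and 1503 FPKM in wild type against 133 and 45.4 FPKM. Of 104 heavy chain V segments, 2 fell and 86 lay below both wild type libraries, with sums of 1538 and 1808 against 568 and 215 FPKM. The last of the 25 was Gm37227, a short immunoglobulin pseudogene listed at 0 in both KO-labelled libraries. Without KO 2 none of these genes passed, although the log2 changes were then -7.60 for Igha, -4.36 for Ighg1, -5.76 for Ighg2c and -3.49 for Ighg2b, against -7.67, -4.32, -5.66 and -3.88 with all libraries. Ighg2b also did not pass without WT 1 (log2 change -3.75), nor did Ighg2c with voom on estimated fragments (adjusted p = 0.0901).

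**Figure D1:**
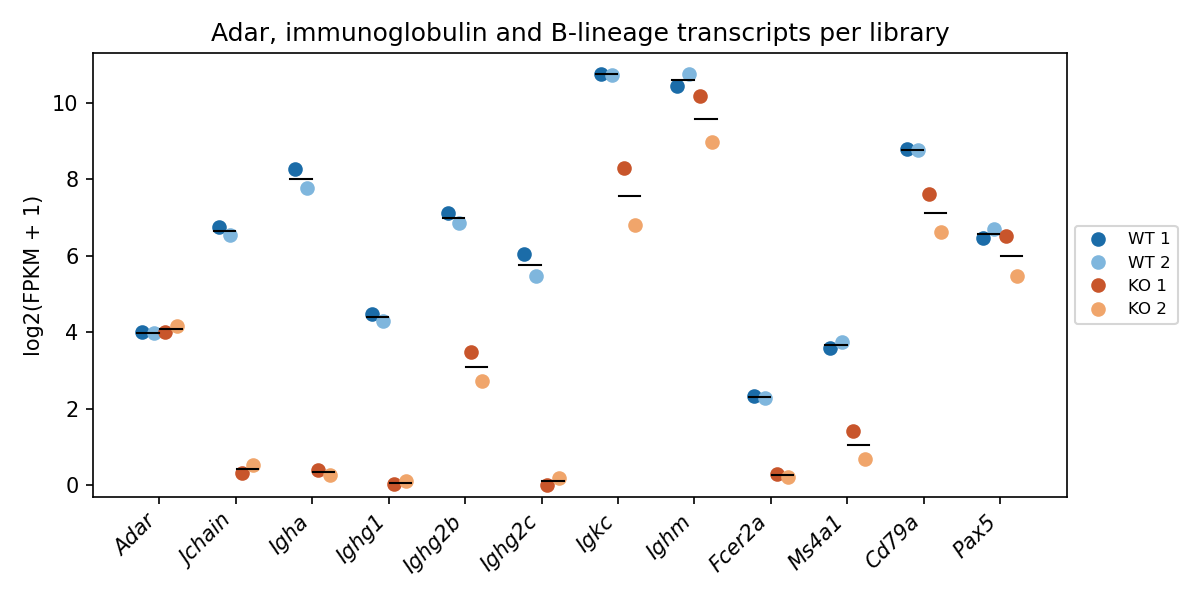
Levels of 12 transcripts as log2(FPKM + 1) in WT 1, WT 2, KO 1 and KO 2, with points for libraries and lines for group means. Jchain, Igha, Ighg1 and Ighg2c lie near 0 in both KO-labelled libraries (0.25 and 0.45 FPKM for Jchain), while Adar lies between 14.62 and 16.79 FPKM in all libraries.

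Genes of maturing B cells were lower as a group. In this list of 39, 37 were tested, 27 were negative (61.7% of all genes were), and 21 were below both wild type libraries in both KO-labelled libraries. Over all genes tested 1 fell (Fcer2a), and 5 fell when adjusted over the list alone. Ms4a1, which encodes the B cell surface protein CD20, was at 11.01 and 12.32 FPKM in wild type against 1.66 and 0.60 FPKM (log2 change -2.62 ± 0.28, adjusted p = 0.0701 over all genes in limma). It passed with the replicate block (0.0271), the crossed block (0.00093), B-lineage scaling (0.0144) and without KO 1 (0.0426). H2-DMb2, part of the peptide loading machinery of MHC class II, was at 10.36 and 10.08 against 4.3 and 4.2 FPKM, and the inhibitory receptor gene Btla was at 10.60 and 13.99 against 4.07 and 3.21 FPKM, and both passed only without KO 1 (adjusted p = 0.0432 and 0.0493) and with the crossed block (0.0276 and 0.00582). The list had a median log2 change of -0.40 and an adjusted camera p of 0.00408, against an adjusted p of 0.528 with an estimated correlation. The B-lineage identity list had the same median of -0.40, and the neutrophil list rose (0.46 in KO 1 and 1.5 in KO 2). Scaling to the B-lineage list moved the median of maturing B cell genes to -0.19. That scaling shifts the median of all genes by 0.24, so the move by itself does not show that B cell dilution lowered this list. The plasma cell marker list, in which Jchain fell and Tnfrsf17 was listed at 0 in both KO-labelled libraries (2.17 and 1.79 FPKM in wild type), had an adjusted camera p of 0.0518 and an adjusted p of 0.511 with an estimated correlation. It was past the threshold in 12 of 18 settings, among them the replicate block (0.0222), no filter (0.00833) and B-lineage scaling (1.41e-05), and further from it without KO 1 (0.143), without KO 2 (0.179) and with the stricter filter (0.392). Its fry test gave an adjusted p of 0.0481, with a median log2 change of -0.77 and 6 of 10 members below both wild type libraries. Ly6c2, a member also expressed by monocytes, was at 84.05 and 71.63 against 104.16 and 228.06 FPKM. Without KO 1 Ly6c2 and Tnfrsf17 passed (adjusted p = 0.0427 and 0.0473), and Tnfrsf17 also with the crossed block (0.0312).

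B-lineage identity genes were lower chiefly in KO 2. Of 34 members 0 passed, 30 were negative and 17 were below both wild type libraries in both KO-labelled libraries, with a list median of -0.15 in KO 1 and -0.83 in KO 2 on the log2 scale. Pax5, the factor that commits cells to the B lineage, was at 86.51 and 102.41 FPKM in wild type against 90.21 and 42.91 FPKM, and Ebf1, its partner in B cell specification, at 30.70 and 36.54 against 32.52 and 17.23 FPKM. Cd79a, the Ig-alpha signalling chain (ENSMUSG00000003379, chromosome 7, 24897381 to 24902197), was at 436.24 and 435.96 FPKM in wild type against 193.59 and 96.80 FPKM, the lowest change of the list in both KO-labelled libraries. Its log2 change of -1.66 ± 0.35 did not pass over all genes (adjusted p = 0.294, limma). Erg, at 28.79 and 27.77 against 44.13 and 42.73 FPKM, Spi1, at 56.12 and 48.98 against 72.59 and 109.53 FPKM, and Bank1, at 2.90 and 3.10 against 1.23 and 1.53 FPKM, did not pass either, and Erg and Spi1 also act in other blood lineages. Without KO 1 Cd79a, Spi1 and Pax5 passed (adjusted p = 0.0426, 0.0490 and 0.0493). The list test gave an adjusted camera p of 0.00243, an adjusted p of 0.621 with an estimated correlation, and 0.106 without KO 2. The neutrophil marker list moved the other way in the same libraries, with medians of 0.46 in KO 1 and 1.5 in KO 2.

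**Figure D2:**
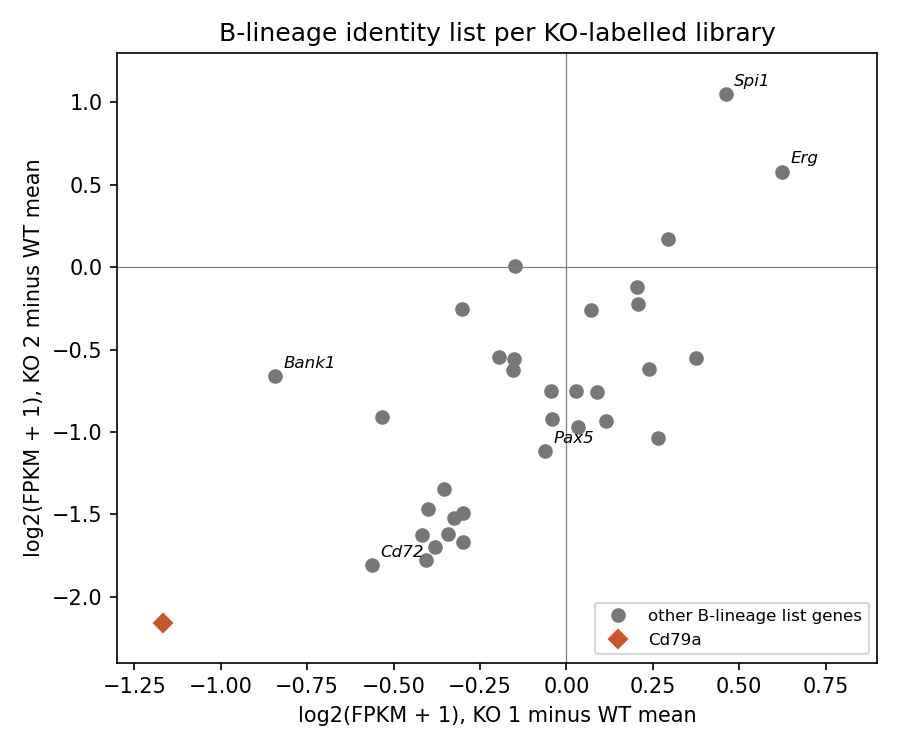
Change in log2(FPKM + 1) of the 34 B-lineage identity genes, KO 1 minus the wild type mean on the x axis and KO 2 minus the wild type mean on the y axis, one point per gene. Cd79a is lowest on both axes, at -1.17 and -2.16.

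Genes of the pro-B stage and the pre-B cell receptor did not pass as a list. Of 30 tested 0 passed and 20 were negative, a share near the 61.7% of all genes. The list median was 0.04 in KO 1 and -0.55 in KO 2 (adjusted camera p = 0.910, adjusted p = 0.974 with an estimated correlation). Igll1 and Vpreb1, which encode the surrogate light chain, were at 204.32 and 189.18 against 198.43 and 134.54 FPKM and at 213.23 and 180.25 against 260.89 and 155.96 FPKM. Rag1 and Rag2, the recombinase of antigen receptor genes, were at 49.79 and 54.84 against 68.02 and 35.27 FPKM and at 16.28 and 16.94 against 16.94 and 9.44 FPKM. For these 4 genes KO 1 and KO 2 lay on different sides of the wild type mean, so the sign of each change depended on the library. Il7r, the interleukin 7 receptor, was at 57.30 and 68.82 against 53.41 and 23.20 FPKM, and Kit, the stem cell factor receptor, at 6.38 and 5.24 against 6.09 and 8.73 FPKM. Bst1, a surface protein of pro-B and stromal cells, was at 18.41 and 18.88 against 28.66 and 28.99 FPKM, Flt3 at 2.87 and 2.16 against 3.45 and 4.83 FPKM, and Hmgb1 at 119.47 and 130.30 against 102.24 and 66.45 FPKM. Without KO 1 Rag2, Il7r and Hmgb1 passed (adjusted p = 0.0491, 0.0473 and 0.0473).

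Interferon-stimulated genes were higher as a group. All 62 members were tested, 0 passed singly, 55 were positive and 36 were above both wild type libraries in both KO-labelled libraries, with a list median of 0.15 in KO 1 and 0.59 in KO 2. Among the 8 members with the smallest p, the oligoadenylate synthetase gene Oas3, whose product senses double-stranded RNA, was at 7.12 and 6.53 FPKM in wild type against 15.04 and 26.79 FPKM, and Oas2 was at 7.63 and 6.90 against 15.32 and 31.49 FPKM (adjusted p = 0.286 and 0.305, limma). Isg15, a ubiquitin-like modifier, was at 15.93 and 13.08 against 23.62 and 37.53 FPKM, and Bst2, which tethers virions, at 84.45 and 62.40 against 112.91 and 121.04 FPKM. Ifit3b was at 1.46 and 1.31 against 3.16 and 8.20 FPKM, Oasl2 at 4.22 and 4.10 against 7.76 and 21.97 FPKM, and Oas1g at 1.76 and 1.61 against 3.75 and 13 FPKM. Without KO 1 Oas3, Oas2, Ifit3b, Oasl2 and Oas1g (adjusted p = 0.0426 for each) and Isg15 (0.0490) passed, and with the crossed block Oas3 (0.0206) and Oas2 (0.0269). The adjusted camera p was 1.25e-11, with an adjusted p of 0.528 with an estimated correlation. The share of fragments from the neutrophil list was 2.89%, 2.70%, 3.84% and 7.63% in WT 1, WT 2, KO 1 and KO 2.

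Sensors of double-stranded RNA and MHC class I genes were slightly higher. Of 26 sensing and editing genes tested 0 passed and 17 were positive, with a list median of 0.09. Ddx58, which encodes RIG-I, was at 7 and 7.3 against 9.49 and 12.30 FPKM, and Zbp1, a sensor of Z-form nucleic acid, at 4.32 and 4.30 against 5.97 and 10.12 FPKM. Dhx58 was at 8.63 and 8.15 against 9.88 and 13.48 FPKM and Sidt2, a transporter of double-stranded RNA, at 22.97 and 26.03 against 29.50 and 34.28 FPKM. Ifih1, which encodes MDA5, was at 3.19 and 2.60 against 2.85 and 5.35 FPKM, Eif2ak2, which encodes PKR, at 11.32 and 12.07 against 11.25 and 16.20 FPKM, and the adaptor gene Mavs at 14.78 and 14.26 against 15.17 and 9.17 FPKM, each with its sign set by KO 2. Of 20 MHC class I presentation genes 16 were positive (list median 0.06), with H2-Q7 at 26.97 and 26.41 against 42.79 and 36.62 FPKM and H2-D1 at 507.07 and 482.37 against 627.58 and 646.94 FPKM. The camera test gave an adjusted p of 0.0270 for sensing and editing and 0.0298 for MHC class I, and the adjusted p was 0.519 for both with an estimated correlation. Neither call held without WT 1 (adjusted p = 0.0557 and 0.0984), without WT 2 (0.0733 and 0.15) or without KO 2 (0.284 and 0.0532), and both were lost with no filter (0.0968 for both). The MHC class I call was also lost without KO 1 (0.0633), with the replicate block (0.0596) and with the crossed block (0.0965), and the sensing call with B-lineage scaling (0.0630). Without KO 1 Zbp1 passed (0.0460). The neutrophil list rose in the same libraries.

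**Figure D3:**
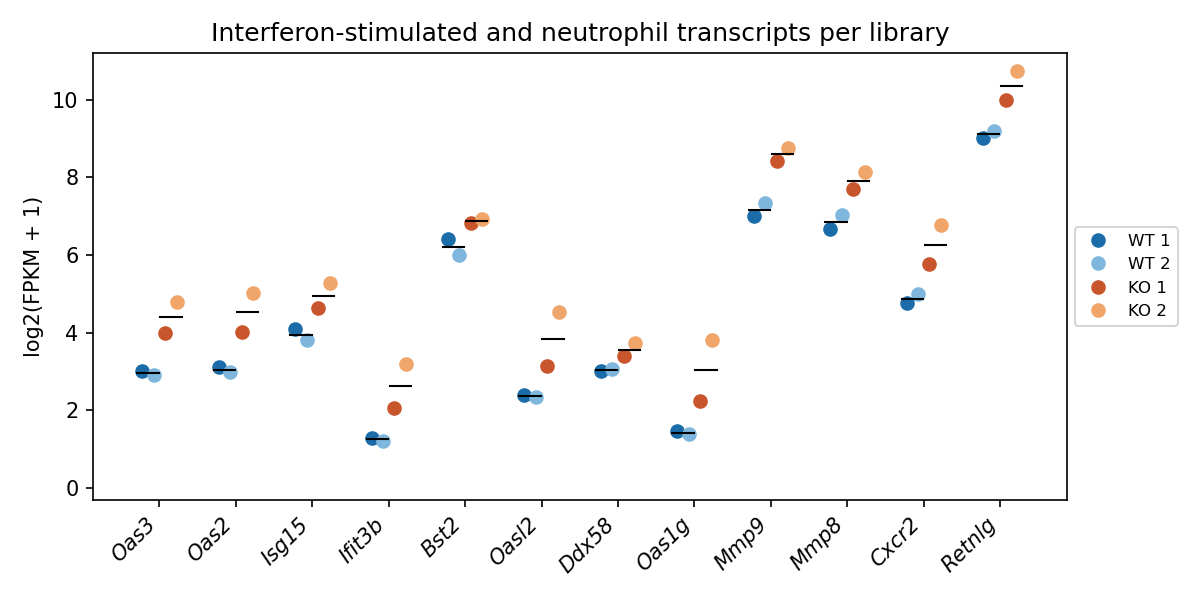
Levels of 8 interferon-stimulated and 4 neutrophil transcripts as log2(FPKM + 1) in each library, with points for libraries and lines for group means. All 12 are higher in both KO-labelled libraries than in both wild type libraries, as for Oas2 at 7.63 and 6.90 against 15.32 and 31.49 FPKM.

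Cell division genes were lower in both KO-labelled libraries. All 45 mitosis genes were below both wild type libraries in both KO-labelled libraries, with medians of -0.36 in KO 1 and -0.45 in KO 2, and 0 passed singly while 24 had an unadjusted p under 0.05. Nusap1, a spindle protein gene, was at 62.46 and 64.42 against 42.44 and 41.39 FPKM, and Ccnb1, which encodes cyclin B1, at 56.72 and 56.35 against 38.23 and 37.26 FPKM. Cenpf and Hmmr were at 20.30 and 23.72 against 14.96 and 13.46 FPKM and at 29.42 and 32.45 against 20.71 and 21.70 FPKM. All 52 genes of DNA replication were negative and 38 lay below both wild type libraries, with medians of -0.16 and -0.54. Rrm1, a ribonucleotide reductase subunit gene, was at 52.68 and 51.97 against 39.77 and 35.52 FPKM, and Lig1, which encodes DNA ligase 1, at 84.16 and 85.16 against 67.37 and 54.64 FPKM. The adjusted camera p was 1.12e-12 for mitosis and 7.94e-08 for replication, and the adjusted p was 0.519 and 0.621 with an estimated correlation. After scaling to the B-lineage list the medians shrank from -0.40 to -0.13 for mitosis and from -0.35 to -0.09 for replication. That scaling shifts the median of all genes by 0.24, so the shrinkage by itself does not show that B cell dilution lowered these lists. It raised KO 2 (log2 factor 0.48) and not KO 1 (-0.20, against -0.11 and -0.17 in WT 1 and WT 2). Both lists stayed past the threshold there (adjusted camera p = 2.79e-06 and 6.77e-05, preset correlation). Camera compares a list with the other genes, which the scaling shifts nearly alike, so this result decides nothing on B cell dilution either. In the same libraries the neutrophil list rose (0.46 in KO 1 and 1.5 in KO 2) and the erythroid list, from another dividing cell type, fell (-1.06 and -0.49). Without KO 1 Lig1 passed (adjusted p = 0.0493).

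Growth and metabolic lists moved in different directions. Oxidative phosphorylation (48 of 49 negative, median -0.22) and ribosome biogenesis (46 of 47 negative, median -0.26) were lower, while glycolysis (21 of 28 positive, median 0.20) and cholesterol synthesis (19 of 24 positive, median 0.16) were higher, with 0 members past the threshold in each. Ndufs1, a complex I subunit gene, was at 14.41 and 14.30 against 11.27 and 10.97 FPKM, and Ncl, which encodes nucleolin, at 124.12 and 125.71 against 108.43 and 80.16 FPKM. Slc2a3, a glucose transporter gene, was at 16.64 and 17.12 against 27.80 and 46.62 FPKM, and the lactate transporter gene Slc16a3 at 11.39 and 10.23 against 18.08 and 33.42 FPKM, while Pfkm was at 12.33 and 9.23 against 6.35 and 6.79 FPKM. Mvd, of the mevalonate pathway, was at 12.49 and 11.70 against 16.13 and 23.19 FPKM. KO 2, the library with the neutrophil list at 1.5, also had the larger medians for glycolysis (0.36, against 0.12 in KO 1) and for ribosome biogenesis (-0.51, against 0.00 in KO 1). The adjusted camera p was 0.000267, 0.000436, 0.000144 and 0.00495 for these lists in the order given. The adjusted p was 0.621, 0.670, 0.519 and 0.528 with an estimated correlation. Scaling to the B-lineage list, used next, shifts the median of all genes by 0.24. Without KO 2 ribosome biogenesis (adjusted p = 0.506) and cholesterol synthesis (0.415) did not pass, nor did oxidative phosphorylation without WT 1 (0.152), nor after scaling to the B-lineage list (0.0672), where its median turned to 0.05. Without KO 1 Slc2a3, Slc16a3, Mvd and Ncl passed (adjusted p = 0.0426, 0.0426, 0.0473 and 0.0495).

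Inflammatory genes of the NF-kappaB response were higher, with 23 of 26 positive, medians of 0.36 in KO 1 and 0.27 in KO 2, and 0 past the threshold. The neutrophil chemoattractant gene Cxcl2 was at 5.63 and 13.84 against 27.96 and 51.32 FPKM and Socs3, a feedback inhibitor of cytokine signalling, at 3.94 and 7.27 against 14.28 and 17.84 FPKM, while Cd83 was at 6.13 and 4.74 against 1.57 and 2.83 FPKM. Cxcl2 passed with the replicate block (log2 change 1.97, adjusted p = 0.0191) and Socs3 with the crossed block (0.0486). Myeloid cells also express Cxcl2 and Socs3, and the neutrophil list rose in the same libraries (0.46 in KO 1 and 1.5 in KO 2). The wild type libraries themselves differed by -0.33 in the median of this list (WT 1 minus WT 2) and by -0.44 in that of the immediate-early and heat shock list. In the latter 15 of 26 were positive, with medians of 0.34 in KO 1 and -0.07 in KO 2, Fos at 50.29 and 85.96 against 117.40 and 161.99 FPKM and Ier3 at 6.04 and 9.64 against 16.97 and 19.24 FPKM. Of 29 genes of interleukin 7 receptor signalling 15 were positive, with medians of 0.16 in KO 1 and -0.07 in KO 2, and the smallest p values included those of Socs3, of the cytokine gene Osm at 9.61 and 15.66 against 28.12 and 37.37 FPKM and of Jak3 at 13.81 and 14.92 against 21.54 and 20.55 FPKM, while Il7r itself was below both wild type libraries in both KO-labelled libraries. For the list tests the adjusted camera p was 6.47e-06, 0.0143 and 0.0114 for NF-kappaB, immediate-early and interleukin 7 receptor genes, and the adjusted p was 0.519, 0.621 and 0.519 with an estimated correlation. The immediate-early call was lost without WT 1 (adjusted p = 0.778), without KO 1 (0.612) or with no filter (0.117), and the interleukin 7 receptor call without WT 1 (0.0655) or KO 1 (0.423).

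Stress lists had no member past the threshold. Targets of ATF4, the factor of the integrated stress response, had 19 of 37 positive, a median of 0.25 in KO 1 and -0.15 in KO 2, and examples in Trib3 at 1.25 and 1.58 against 5.88 and 3.67 FPKM, Chac1 at 1.58 and 1.00 against 3.39 and 4.89 FPKM and Atf5 at 7.33 and 6.05 against 16.06 and 11.84 FPKM. Apoptosis regulators had 23 of 41 positive (median 0.15), with the p53-induced BH3-only gene Bbc3 at 3.28 and 2.84 against 8.05 and 5.67 FPKM and the death receptor gene Fas at 2.39 and 2.42 against 3.58 and 5.16 FPKM. Targets of p53 had 14 of 33 positive, a median of -0.06 and a mean of 0.00, with a test direction of higher, and included Ephx1 at 8.86 and 8.53 against 5.41 and 3.26 FPKM. Genes of the unfolded protein response had 13 of 28 positive, a median of 0.00 and a mean of -0.06 below 0 with a test direction of higher, and included Derl3 at 4.86 and 3.33 against 2.09 and 0.90 FPKM. The medians of the p53 and unfolded protein lists turned positive with quantile normalization, median centring or B-lineage scaling (0.17 and 0.26 for the last, which shifts the median of all genes by 0.24). Camera gave adjusted p of 0.0143, 0.0296, 0.603 and 0.825 for ATF4, apoptosis, p53 and unfolded protein genes, and the adjusted p was 0.621, 0.519, 0.827 and 0.955 with an estimated correlation. The ATF4 call was lost without KO 1 (adjusted p = 0.8998), and the apoptosis call without WT 1 (0.0870), WT 2 (0.0674) or KO 2 (0.417), with no filter (0.0968) or with B-lineage scaling (0.0630). Trib3 and Chac1 passed with the crossed block (0.0342 and 0.0394) and Ephx1 without KO 1 (0.0432).

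Markers of other marrow cells differed between the libraries. All 22 neutrophil genes were positive and 18 lay above both wild type libraries, with 0 past the threshold over all genes and 7 that rose when adjusted over the list alone. Mmp9, the granule gelatinase gene, was at 128.07 and 159.43 against 341.98 and 429.82 FPKM, Mmp8 at 100.86 and 130.52 against 205.35 and 279.33 FPKM, Cxcr2 at 26.01 and 30.84 against 53.02 and 107.30 FPKM, and Retnlg at 512.77 and 586.32 against 1016 and 1690 FPKM. All 21 erythroid genes were negative, with a median of -1.06 in KO 1 and -0.49 in KO 2 and a difference of 0.71 between WT 1 and WT 2, as in Hba-a1 at 450.46 and 273.06 against 110.71 and 213.36 FPKM. Plasmacytoid dendritic cell genes were higher (15 of 17 positive), with 1 that rose when adjusted over the list alone, Cox6a2 at 13.77 and 10.12 against 26.83 and 26.94 FPKM, and with Bst2 shared with the interferon list. NK cell genes were higher (13 of 16 positive, medians of 0.12 in KO 1 and 0.24 in KO 2), and stromal genes had 8 of 10 positive but medians of -0.18 in KO 1 and 0.82 in KO 2, with 3 of 10 above both wild type libraries, with Nkg7 at 26.52 and 22.46 against 27.77 and 79.15 FPKM and Cdh5 at 1.43 and 1.77 against 2.87 and 3.32 FPKM. The adjusted camera p was 9.59e-12, 1.92e-06, 6.57e-05, 0.0111 and 0.0185 for neutrophil, erythroid, plasmacytoid, NK and stromal genes, and the adjusted p was 0.511 for all 5 with an estimated correlation. The erythroid call was lost without KO 1 (adjusted p = 0.141), and the NK and stromal calls without WT 2 (0.293 for both), without KO 2 (0.316 for both) or with B-lineage scaling (0.0519 and 0.168). The stromal call was also lost with no filter (0.258), where the median fell from 0.58 to 0.03, with the stricter filter (0.186) and with median centring (0.0503). Without KO 1 Mmp9, Cxcr2, Retnlg and Nkg7 passed (adjusted p = 0.0473, 0.0426, 0.0429 and 0.0426), and Cox6a2 with the crossed block (0.0395).

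The remaining cell type lists did not pass with all libraries, and some passed with 1 left out. Stem and progenitor genes had an adjusted camera p of 0.0518 (8 of 13 positive, Csf2rb at 14.94 and 14.35 against 21.97 and 46.63 FPKM), and genes of basophils, mast cells and eosinophils 0.0730 (10 of 17 positive, Hdc at 17.25 and 20.06 against 33.76 and 55.86 FPKM). T cell genes had 0.300 (7 of 12 positive), conventional dendritic cell genes 0.320 (7 of 11 positive, Siglecg at 63.73 and 70.22 against 46.25 and 29.69 FPKM), megakaryocyte genes 0.300 (3 of 8 positive) and monocyte and macrophage genes 0.427 (10 of 22 positive, Cd163 at 15.76 and 9.18 against 4.46 and 5.79 FPKM). Siglecg fell further in KO 2, as the B-lineage identity list did (medians of -0.15 in KO 1 and -0.83 in KO 2), so its fall may not reflect dendritic cells. Clec10a of the same dendritic cell list was at 4.10 and 3.55 against 5.36 and 7.23 FPKM. For conventional dendritic cells the mean was -0.01 against a median of 0.24, and for megakaryocytes and monocytes the medians were -0.07 and -0.03 against means of 0.11 and 0.01, with a test direction of higher in all of these. The monocyte list moved in opposite directions, with medians of -0.56 in KO 1 and 0.35 in KO 2, and passed as higher without KO 1 (adjusted p = 0.000262) and as lower without KO 2 (0.0326). Without KO 1 the megakaryocyte (0.00760), stem and progenitor (0.0122) and basophil (0.0366) lists also passed as higher, as did the stem and progenitor (0.0318) and basophil (0.0344) lists without WT 1 and the stem and progenitor list with voom (0.0495). Csf2rb, Hdc and Siglecg passed without KO 1 (0.0426, 0.0426 and 0.0428) and Cd163 with the crossed block (0.0386). Among sex-linked genes, Xist was at 108.45, 117.28, 94.87 and 83.48 FPKM in WT 1, WT 2, KO 1 and KO 2, while Ddx3y, Kdm5d and Uty were listed at 0 in all libraries and Eif2s3y at 0.02 FPKM in KO 2 and 0 in the others.

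**Figure D4:**
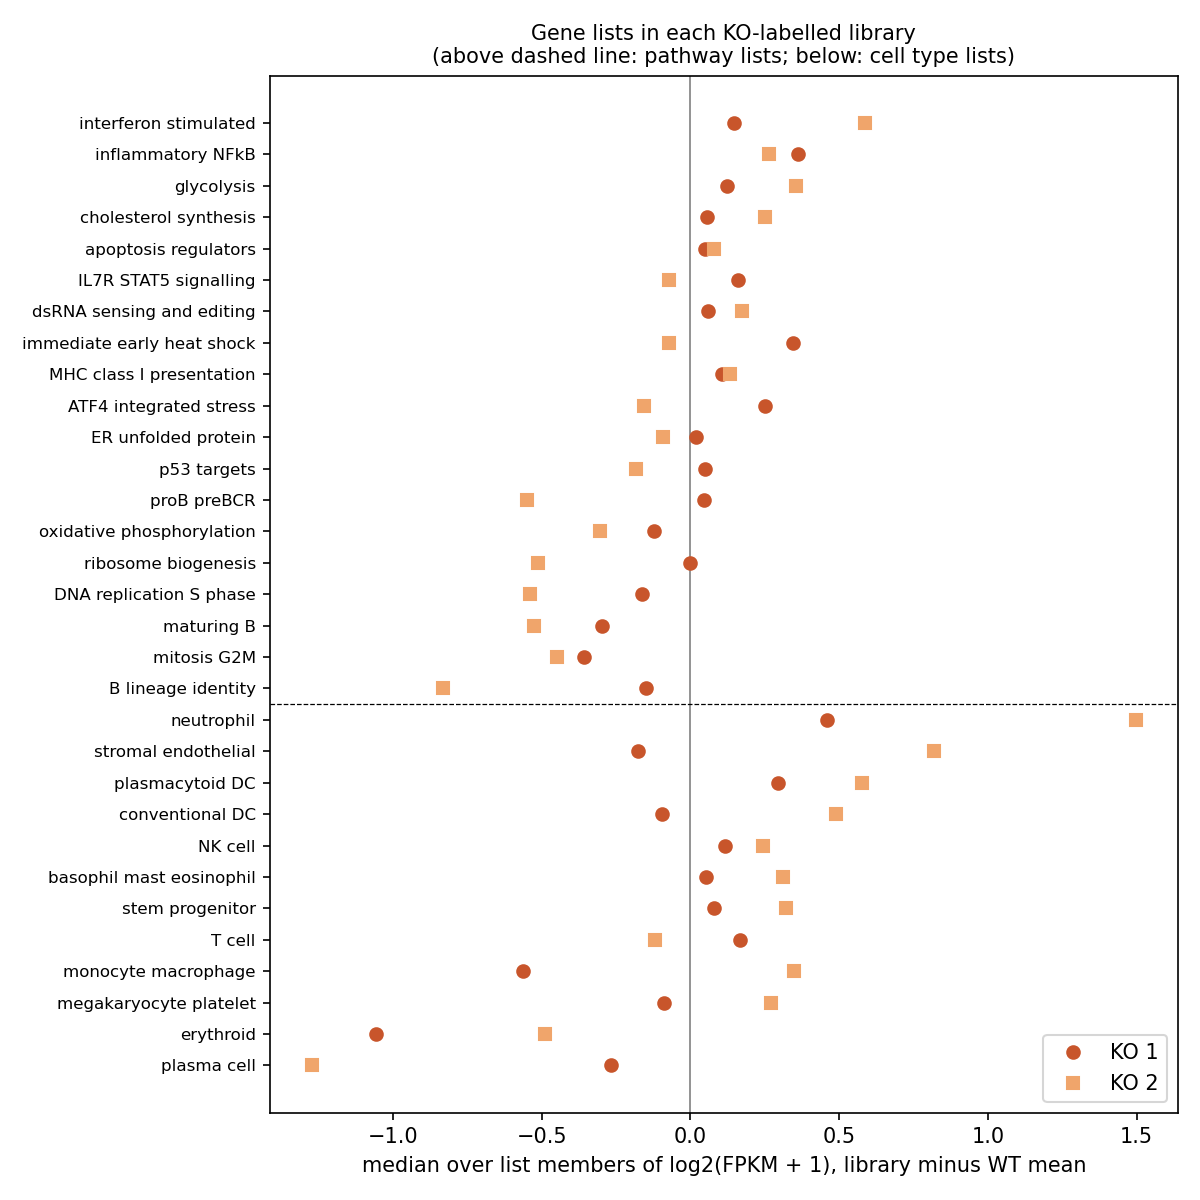
Median over the members of each gene list of the change in log2(FPKM + 1), KO 1 (circles) and KO 2 (squares) minus the wild type mean, with pathway lists above the dashed line and cell type lists below it. Neutrophil genes are highest in both (0.46 and 1.5), and erythroid genes are below 0 in both (-1.06 and -0.49).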

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

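The block and the estimated-correlation and fry tests were planned, while the tests with voom, B-lineage scaling, rescaling without the neutrophil list and the crossed block were chosen after the results were seen. The Adar change kept its direction and stayed short of the threshold in every alternative, with log2 changes of 0.03 to 0.17 when 1 library was left out. Of 27 genes lower and 0 higher, leaving out 1 library gave 0 to 948 genes, with 0 to 563 higher and 0 to 385 lower, where the lone library of an arm is assumed to vary like the other arm. All 27 were negative without KO 2, where none passed. Their median log2 change was -3.49 without KO 2 and -3.90 without KO 1, with a median unadjusted p of 0.000212 and 0.000123 and a median adjusted p of 0.152 and 0.0426, as 1969 and 5380 of all genes had an unadjusted p under 0.05. No filter gave 0 genes over 26648 tested, a pseudocount of 0.1 gave 15 lower, voom on estimated fragments gave 9 lower, and B-lineage scaling, which shifts the median of all genes by 0.24, gave 66 lower. The stricter filter and the fit without a trend each added 1 higher gene, while quantile normalization, median centring, the minimum log2 change and rescaling without the neutrophil list left the counts within 1.5 times. The cause was not tested where construction does not give it. The replicate numbers share no stated origin and their deviations correlated at -0.15 across genes. The replicate block gave 68 genes (7 higher, 61 lower). The crossed replicate block gave 213 genes (46 higher, 167 lower). Of pathway lists 16 passed, against 10 to 13 with 1 library left out, and of cell type lists 5, against 4 to 8. With an estimated correlation 0 of either kind passed, and with fry 0 and 1. The former has 2 residual degrees of freedom and gave no unadjusted p below 0.113. Its losses therefore do not show that correlation between genes removed the calls. Apoptosis regulators, with an estimated correlation of -0.0033, below the preset, went from an unadjusted camera p of 0.0234 to 0.115. No named gene that turned sign was past the threshold there or before. Leaving out 1 library, log2 changes ranged from -0.54 to 0.013 for Igll1, -0.33 to 0.41 for Vpreb1, -0.55 to 0.37 for Rag1, -0.75 to 0.027 for Rag2, -0.013 to 0.71 for Ifih1, -0.051 to 0.44 for Eif2ak2 and -0.61 to 0.059 for Mavs. B-lineage scaling gave 0.016 for Atf6, 0.0090 for Igll1 and 0.18 for Rag1. List directions also turned, and leaving out 1 library gave adjusted p from 0.0633 to 0.981 for pro-B genes, 0.346 to 0.8998 for p53 targets, 1.78e-05 to 0.8998 for ATF4 targets, 0.663 to 0.981 for unfolded protein genes, 0.000262 (higher, without KO 1) to 0.293 for monocyte genes, which passed as lower without KO 2 (0.0326), 0.0743 to 0.882 for conventional dendritic cell and 0.00760 to 0.882 for megakaryocyte genes. With other settings, turned directions had adjusted p of 0.888 (p53 targets) and 0.722 (unfolded protein) with fry, 0.683 (unfolded protein) with no filter, 0.954 (B-lineage scaling) and 0.951 (fry) for monocyte genes, and 0.855 for conventional dendritic cell genes with B-lineage scaling. Over 2094 values of named genes, 2001 kept direction and side, 61 passed where they had not, 21 no longer passed and 11 turned. Depth limits low genes, since 3 fragments on 1000 nt are worth 0.183 to 0.198 FPKM.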

Other observations

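All tests in the paragraphs on immunoglobulin, interferon and Cd79a transcripts below were chosen after the results were seen, as were the genes of this and the next paragraph. At an adjusted p under 0.1 in limma there were 54 lower genes, 27 of them past the threshold of 0.05, and 6 higher genes, of which 0 were past it. Of the higher ones, the following are in none of the lists. Acvrl1, which encodes the BMP9 receptor ALK1, was at 6.62 and 7.47 FPKM in wild type against 20.69 and 22.14 FPKM (log2 change 1.48 ± 0.14, adjusted p = 0.0555). Asprv1, a retroviral-like protease gene, was at 7.16 and 9.61 against 30.28 and 43.85 FPKM (adjusted p = 0.0935), and Gadd45g, a stress-induced gene, at 11.55 and 13.14 against 29.49 and 28.07 FPKM (adjusted p = 0.0948). Trbj2-6 and Trbj1-7, joining segments of the T cell receptor beta locus, were listed at 0 in both wild type libraries and at 2.63 and 2.76 FPKM and at 4.12 and 8.62 FPKM in KO 1 and KO 2. These segments are short, so such values rest on few fragments.

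Summed kappa V segments lay further below wild type than summed heavy chain V segments. The summed kappa V values stood at 0.999 and 0.831 times the summed heavy chain V values in WT 1 and WT 2, and at 0.235 and 0.211 times in KO 1 and KO 2. Kappa V sums were at 8.78% and 2.98% of the wild type mean in KO 1 and KO 2, and heavy chain V sums at 33.9% and 12.8%. The Fr.C+C′ gate precedes kappa rearrangement in most cells, and the log2 ratio differed by -2.03 ± 0.15 (KO minus WT, SE of a linear model, 95% interval -2.69 to -1.37), which was tested after the ratios were seen. The difference was -1.90 to -2.16 with 1 library left out, where the interval took in 0 without KO 1 or KO 2, and -1.998 with no filter on low values. The exact permutation p was 0.333, the smallest that 3 splits of these libraries can give.

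The fall of immunoglobulin and Jchain transcripts was set against a lower share of B-lineage RNA. In KO 1 the median change of the 27 genes that fell lay at -3.34 relative to that of the B-lineage list. The 27 were called for their fall in these same libraries, so this gap was partly fixed in advance and decides nothing on dilution. Kappa V segments as a class, not only those called, summed to 8.78% and 2.98% of the wild type mean in KO 1 and KO 2. The B-lineage list had medians of -0.15 and -0.83 there, with an SD of its members of 0.37 and 0.72. For kappa V transcripts, an equal dilution of all B-lineage RNA is therefore argued against. Loss of plasma cells, which make Jchain, Igha and the IgG transcripts and which the sort should remove, may account for the fall of those transcripts. The maturing B cell list, which holds Fcer2a and Ms4a1, was lower too (median -0.40), and whether plasma cell loss bears on that list was not tested. The plasma cell list without Jchain gave a fry p of 0.0536 over 9 members, of which 5 were below both wild type libraries. Among these 5, Tnfrsf17 was at 2.17 and 1.79 against 0 and 0 FPKM and Derl3 at 4.86 and 3.33 against 2.09 and 0.90 FPKM. Xbp1 and Mzb1 were not among them, at 45.61 and 39.29 against 47.08 and 55.40 FPKM and at 39.22 and 37.55 against 50.87 and 28.14 FPKM. The plasma cell list is too small to settle whether plasma cells were lost, and it shares Irf4 with the B-lineage list. An effect of the genotype on B cells and a difference in how the gate was set between groups stay open and were not tested.

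The higher interferon-stimulated list may reflect more neutrophil RNA, or an interferon response in the sorted cells, whose link to the genotype was not tested. Its median in KO 2 lay at -0.91 relative to that of the neutrophil list, and in KO 1 it was 0.15 against 0.46, so a larger neutrophil share that carries interferon-stimulated transcripts cannot be told apart from a response, because the neutrophil list exceeds it in both libraries. S100a9, the most abundant neutrophil gene, was at 11647 and 11187 FPKM in wild type against 15796 and 32346 FPKM, although the sort should remove neutrophils. In KO 2, Oas1g and Oasl2 exceeded every gene of the neutrophil list, at 2.38 and 2.15 against a highest value of 2.05, but in that library alone. The erythroid median lay at -1.51 or further below the neutrophil median in both KO-labelled libraries, beyond the spread between member genes. This argues only against a lower B-lineage share that raises every other cell type alike. The erythroid median also differed by 0.71 between WT 1 and WT 2. The gap therefore cannot decide whether a lower B-lineage share, with erythroid RNA varying separately, raised the interferon-stimulated list.

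Cd79a was lower than the other B-lineage genes in both KO-labelled libraries, at -1.17 in KO 1, where the next lowest member was Bank1 at -0.84, and at -2.16 in KO 2, where it was Cd72 at -1.81. The gene was chosen for its low value, and 1 of 34 members has to be lowest. Its distance to the next member in KO 2 (-0.35) is within the SD of the other members (0.69), so a lower share of B-lineage RNA with the usual spread between genes cannot be told apart from a change of Cd79a itself. An allele of Cd79a interrupted in the mice labelled KO, for example by a Cre recombinase inserted at this locus, may also lower it, a design that the labels do not state. Relative to the median of the other 33 members Cd79a stood at -1.02 and -1.41, a mean of -1.21. This neither supports nor excludes the loss of 1 of 2 alleles (-1), since the gene was picked for its low value. The SD of the other members in KO 2 (0.69) also lets many low values agree, while that in KO 1 (0.33) is narrower. Lower transcription of the gene stays open.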
